A study of synthetic construct and Homo sapiens with 13 samples.

How the data were processed

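The analysis used 6 RNA-seq libraries of BT20 cells, 3 treated with DMSO and 3 with 10 µM erlotinib for 24 h. Messenger RNA libraries were made with a stranded kit, per the labels' protocols; whether strand was used in counting is not given in the sources used here. The 7 CRISPR screen samples of the series measure guide abundance in genomic DNA, a different assay, and were not used here.

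The authors deposited RSEM expected counts per gene, which are estimated counts that divide a read among the genes it matches, and TPM values, which scale those counts by effective gene length to the same total in every library. Per the submitters' processing notes, FastQC 0.11.8, Bowtie2, RSEM 1.3.1 and DESeq2 1.26.0 were used, and the builds hg19 and GRCh38 are both named. Which build belongs to these tables is not given in the sources used here, so no coordinates are printed. Rows pair a gene symbol with RefSeq transcripts, per the file headers. A further deposited table holds the authors' DESeq2 log2 fold changes with p-values and adjusted p-values. Its positive log2 fold changes mean higher in erlotinib, since 100% of its called genes that were tested here had mean CPM in that direction. Shrinkage of these fold changes by the authors is not given in the sources used here.

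Library totals ranged from 13599307 to 20660281 expected counts. In the files 13.9% of the values were not whole, and all were rounded to whole numbers, which moves a value by at most 0.5. Because RSEM divides reads between similar or overlapping genes, values of paralogs, readthrough genes and multicopy families are uncertain. Within each group every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 2.11 or more), so no library was counted as a duplicate.

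Genes were filtered with filterByExpr, normalised by TMM and tested with edgeR 4.0.16 (glmQLFit, glmQLFTest) under R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over 13312 genes. A gene is said to rise or fall at an adjusted p under 0.05. The standard error is the fitted log2 fold change divided by the square root of its F statistic. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the lists with at least 5 measured members. Before the data were examined, 34 gene lists, the tests and most alternatives were fixed. The rule for named genes was fixed then too: the 12 largest increases and 12 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, up to 4 members of each list with the smallest p, and all members of the ERK and HER lists. Exceptions are marked in the text as chosen after their values were seen.

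The pairing of replicate numbers was checked from the correlation, across genes, of each library's deviation from its group mean. It was 0.193, 0.191 and 0.519 for replicates 1, 2 and 3, all above 0.1, so the numbers were treated as possible pairs. The main fit, with its counts and p-values, does not use this pairing. Results of a fit with the replicate block are given where they change a call or a count by over 1.5 times. The labels name no shared batch or day. DMSO replicate 1 correlated slightly more with erlotinib replicate 2 (0.209) and DMSO replicate 2 with erlotinib replicate 1 (0.244). These unmatched pairs also lie above 0.1, so that limit does not identify pairs. The shared part is mainly the difference of replicate 3 from the others. In a principal component analysis the first component (54.4% of variance) separated the treatments and the next (23.3%) separated replicate 3 from replicates 1 and 2.

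The alternatives fixed in advance were DESeq2 1.42.0, median-of-ratios size factors, no filter, a filter at 1 CPM in at least 3 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), limma without a TPM filter, the replicate block, leaving out each library, and for lists an estimated correlation and fry. Alternatives added after seeing the data were leaving out both replicate 3 libraries and offsets that remove a smooth trend of each library on effective length (loess span 0.3), alone and with the replicate block. On simulated counts drawn for erlotinib against DMSO with 13206 genes tested, the edgeR fit recovered 98% of 100 genes changed by 1 on the log2 scale and 36% of 100 genes changed by 0.5, with 2 false calls among 136. On the same counts the fit with the replicate block made 14 false calls among 149, and DESeq2 made 24 among 182 with 13312 genes tested. The counts were drawn with the spread of the fit without the block, plus a shift of replicate 3 that was random across genes. In the data that shift followed transcript length, so the simulation does not give the error rate of the block there. The list tests recovered 2 of 2 shifted lists and called none of the others among 10, with 13219 genes in that simulation. Genes were drawn independently in it. In the data, estimated correlations within the called lists ran from -0.014 (aryl hydrocarbon receptor targets) to 0.198 (NRF2 targets). The simulation therefore does not show how the list tests behave when members are correlated.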

Results

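The series measured the transcriptome of BT20, an established human triple-negative breast cancer cell line that carries extra copies of the epidermal growth factor receptor gene EGFR. Cells received either 10 µM erlotinib, a small-molecule inhibitor of the EGFR tyrosine kinase, or the solvent DMSO for 24 h, with 3 libraries per treatment. Expected counts per library summed to 16809156, 15480255 and 20660281 in DMSO replicates 1 to 3, and to 13599307, 15752787 and 16566436 in erlotinib replicates 1 to 3. Of 25807 gene symbols, 13312 had enough counts to test. A genome-wide CRISPR screen in the same line makes up the other 7 samples of the series and was not analysed here. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are given as mean TPM ± SD over n = 3 libraries, log2 fold changes as erlotinib relative to DMSO with their standard error (SE), and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes are named by the symbols of the deposited tables.

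The comparison asks which transcripts differ in these cells after 24 h of EGFR inhibition. EGR1, an immediate early transcription factor induced by growth factor signalling, fell from 21.1 ± 1.63 to 1.16 ± 0.493 TPM, an 18.6-fold decrease (log2 fold change -4.22 ± 0.21, adjusted p = 2.64e-05). The ETS factors ETV4 and ETV5 fell 7.15-fold and 6.47-fold, to 4.40 ± 0.339 and 5.94 ± 0.409 TPM. Asparagine synthetase, encoded by ASNS, rose 5.37-fold, from 23.3 ± 1.98 to 129.8 ± 1.88 TPM (log2 fold change 2.42 ± 0.08, adjusted p = 5.45e-06). The cytochrome P450 gene CYP1A1 rose 5.60-fold, from 8.83 ± 0.968 to 50.8 ± 2.42 TPM. In all, 1477 genes were higher and 1288 lower with erlotinib at an adjusted p under 0.05, which is 20.8% of the genes tested. At least 2-fold changes were fewer, with 198 genes higher and 123 lower. With the replicate number as a block, 2818 genes were higher and 2844 lower, and these included all 2765 genes called without it. On simulated counts the fit with the block made 14 false calls among 149, against 2 among 136 without it. The simulated shift of replicate 3 was random across genes, unlike that in the data, so these numbers do not give the block's error rate there. The 3 values of one group lay entirely above or below those of the other in 39.6% of tested genes, against 10% by chance. Leaving out libraries changed the numbers of genes called. They were 768 higher and 722 lower without DMSO replicate 1, and 884 and 755 without DMSO replicate 2. Without erlotinib replicate 1 they were 688 and 637, and without erlotinib replicate 2, 783 and 757. They were 1192 and 1159 without DMSO replicate 3, 1627 and 1734 without erlotinib replicate 3, and 2681 and 2849 without both replicate 3 libraries. The lowest numbers came where a group kept replicate 3 and 1 other library. Without erlotinib replicate 3, 196 genes were at least 2-fold lower.

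The other large increases include CHAC1, which like ASNS belongs to the list of genes controlled by the transcription factor ATF4, described below. Whether the others share a regulator was not tested. ALDH1L2, a mitochondrial folate enzyme, rose from 0.920 ± 0.238 to 6.65 ± 0.807 TPM, and VTCN1, the immune checkpoint ligand B7-H4, from 5.73 ± 1.08 to 38.9 ± 3.58 TPM. ADM2 (adrenomedullin 2) reached 19.7 ± 1.39 TPM from 3.10 ± 0.225, and the stress-induced regulator NUPR1 reached 540.3 ± 20.03 TPM from 101.8 ± 8.93. S100P, a calcium-binding protein gene, rose 5.23-fold, and CHAC1, which degrades glutathione, 5.04-fold. PELI2, LBH and the long noncoding RNA LINC01133 rose between 5.59-fold and 5.99-fold. RAB4B-EGLN2 had the largest fitted log2 fold change among the genes named by rule, 3.93 ± 0.83, but it is a readthrough gene that shares sequence with its neighbouring genes, so its reads are uncertain. Its expected counts were 0, 0 and 25.5 in DMSO, and DESeq2 gave it an adjusted p of 0.174; without DMSO replicate 3 its fitted log2 fold change was 9.88, set by the prior count against counts of 0.

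Among the largest decreases, the AP-1 subunits FOSL1 and FOS fell 4.94-fold and 4.82-fold, to 4.60 ± 1.78 and 1.39 ± 0.245 TPM. MYEOV fell from 21.5 ± 2.13 to 5.35 ± 1.25 TPM, and the cytokine gene LIF from 23.3 ± 1.71 to 6.52 ± 1.33 TPM. SRPX2, the transglutaminase gene TGM2 and the xanthine dehydrogenase gene XDH fell 3.60-fold, 3.59-fold and 3.39-fold. LOC100132287 fell 3.78-fold, and this call was lost without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2 (adjusted p 0.0653 to 0.0903), while its log2 fold change of -1.92 was -3.01 without erlotinib replicate 3.

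**Figure D1:**
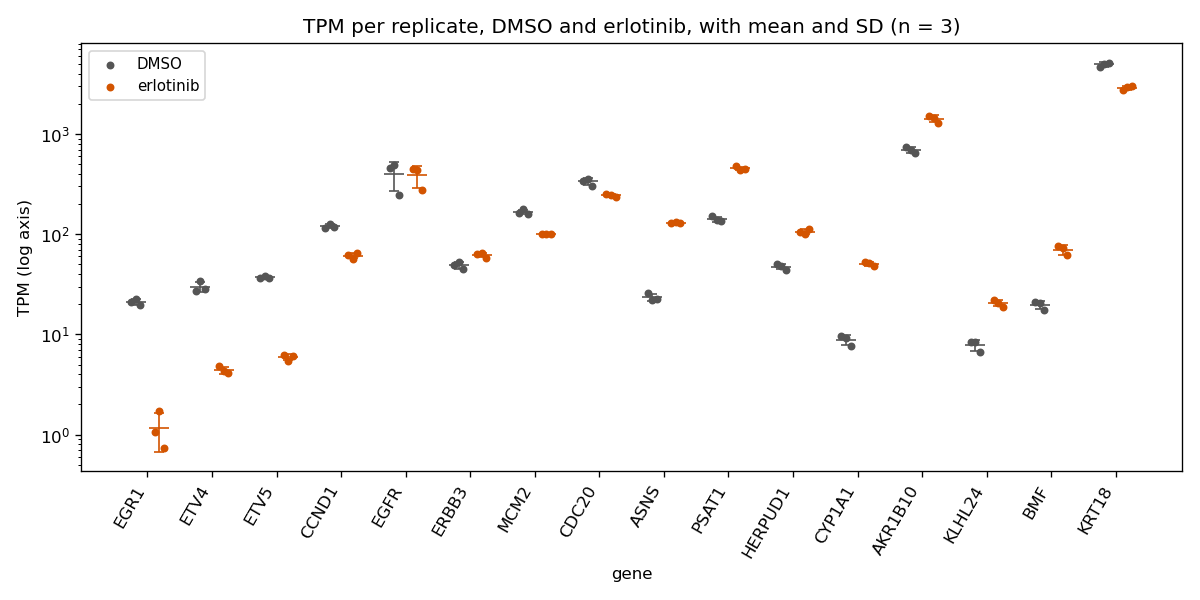
TPM on a log axis for 16 genes, with a point per library, horizontal bars for the mean and whiskers for the SD (n = 3 per group); DMSO is grey and erlotinib orange. EGR1 drops from a mean of 21.1 to 1.16 TPM and ASNS climbs from 23.3 to 129.8 TPM, while the EGFR points of the groups overlap.

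Transcripts that report output of the ERK kinase pathway fell almost as a group. Of 19 measured members, 17 fell, SPRED3 rose and EPHA4 did not pass; adjusted over the list alone, 18 fell and 1 rose. The list median was -1.39 on the log2 scale (camera adjusted p = 7.94e-15; adjusted p = 0.103 with an estimated correlation). The dual-specificity phosphatase genes DUSP4 and DUSP5, which encode MAP kinase phosphatases, fell to 14.6 ± 2.01 and 7.24 ± 0.617 TPM from 37.0 ± 1.16 and 16.9 ± 0.741. SPRY4, SPRED1 and SPRED2, inhibitors of receptor and RAS signalling, fell 6.96-fold, 3.19-fold and 3.08-fold, and SPRY2 1.72-fold. Cyclin D1 (CCND1) fell 2.03-fold, from 120.4 ± 6.06 to 61.1 ± 3.78 TPM. ETV1, EPHA2, PHLDA1, DUSP7 and IER3 also fell, by 3.03-fold, 1.94-fold, 1.84-fold, 1.69-fold and 1.80-fold, and the IER3 call was lost without erlotinib replicate 1 or 2 (adjusted p 0.0875 and 0.0883). EPHA4 stood at 1.503 ± 0.248 TPM in DMSO and 0.987 ± 0.258 in erlotinib (adjusted p = 0.0554, and 0.00827 with the replicate block). DUSP6 was low in every library, at 0.763 ± 0.231 TPM in DMSO and 0.227 ± 0.155 in erlotinib, and its decrease was no longer called without DMSO replicate 1, DMSO replicate 3 or erlotinib replicate 1 (adjusted p 0.0584 to 0.0783). SPRED3, at 0.760 ± 0.11 and 1.47 ± 0.175 TPM, lost its call without DMSO replicate 1 or erlotinib replicate 1 (adjusted p 0.0519 and 0.0573).

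Immediate early genes fell in part. Of 15 measured, 5 fell and 10 did not pass, 6 fell adjusted over the list alone and 8 without erlotinib replicate 3; the list median was -0.31, and -0.48 without erlotinib replicate 3 (camera adjusted p = 0.000677; adjusted p = 0.170 with an estimated correlation). Besides EGR1 and FOS, KLF6 fell from 18.3 ± 1.85 to 12.02 ± 0.515 TPM and the nuclear receptor gene NR4A1 from 7.57 ± 0.927 to 5.16 ± 0.227 TPM. The remaining one, JUN, was chosen after its values were seen and fell from 28.2 ± 1.51 to 14.5 ± 4.33 TPM (adjusted p = 0.0124).

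EGFR itself did not differ detectably. Its level was 398.6 ± 131 TPM in DMSO and 386.9 ± 95.7 TPM in erlotinib (log2 fold change -0.08 ± 0.23, adjusted p = 0.848), with the lowest value of each group in replicate 3, 248.8 and 276.8 TPM. Its log2 fold change was 0.02 without DMSO replicate 1, 0.07 without DMSO replicate 2 and 0.10 without erlotinib replicate 3. ERBB3, the HER3 receptor, rose from 48.9 ± 3.95 to 62.1 ± 3.12 TPM (adjusted p = 0.00414). ERRFI1, a feedback inhibitor of EGFR, fell from 82.2 ± 5.28 to 43.5 ± 2.09 TPM, and the ligand gene EREG (epiregulin) from 7.20 ± 1.00 to 2.98 ± 0.572 TPM. Of 13 measured receptors, ligands and feedback genes, 2 rose and 3 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.379). The amphiregulin gene AREG fell 1.94-fold, a call lost without DMSO replicate 1 or erlotinib replicate 1 (adjusted p 0.0520 and 0.0554). Betacellulin (BTC) rose 1.63-fold, a call lost without any one of the 6 libraries (adjusted p 0.0539 to 0.102) and in DESeq2 (adjusted p = 0.138). ERBB2 measured 96.0 ± 7.06 and 109.6 ± 4.75 TPM (adjusted p = 0.0912, and 0.0167 with the replicate block), HBEGF 1.39 ± 0.360 and 0.807 ± 0.183 TPM, and TGFA 32.6 ± 3.27 and 31.3 ± 3.82 TPM in DMSO and erlotinib. EPGN, EGF, LRIG1 and LRIG3 had adjusted p-values of 0.301, 0.646, 0.905 and 0.844. ERBB4, NRG1, NRG2 and NRG4 were too low to test.

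Among 15 other receptor tyrosine kinases, 2 rose and 3 fell, also when adjusted over the list alone, and 7 fell with the replicate block (camera adjusted p = 0.362). Without DMSO replicate 1 or erlotinib replicate 1, 1 rose. The collagen receptor gene DDR2 rose from 0.350 ± 0.0900 to 1.17 ± 0.169 TPM. MST1R, which encodes the RON receptor, fell from 23.8 ± 2.31 to 15.4 ± 0.699 TPM, and the ephrin receptor gene EPHB4 from 19.8 ± 1.15 to 11.5 ± 1.04 TPM.

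Genes of DNA replication fell by modest factors in nearly every case. Of 27 measured members of the replication and E2F list, 25 fell and none rose, and all 27 fell adjusted over the list alone; the list median was -0.49 (camera adjusted p = 7.94e-15; adjusted p = 0.103 with an estimated correlation). The helicase subunit MCM2 fell from 166.5 ± 9.14 to 100.6 ± 0.778 TPM and the GINS subunit GINS2 from 241.4 ± 12.8 to 128.5 ± 4.17 TPM. UHRF1, which maintains DNA methylation, and RRM2, a ribonucleotide reductase subunit, fell 1.81-fold and 1.62-fold. Of the mitotic genes, 18 of 24 fell and 6 did not pass, and 23 fell adjusted over the list alone (median -0.40, camera adjusted p = 4.62e-11; adjusted p = 0.117 with an estimated correlation). CDC20, PLK1, KIF2C and CCNB1 fell between 1.38-fold and 1.43-fold; CCNB1, or cyclin B1, went from 341.7 ± 11.2 to 255.9 ± 10.2 TPM. Of 15 CDK inhibitor and quiescence genes, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone, and 4 fell with the replicate block (camera adjusted p = 0.579). None of these fell without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2, and 1 fell without erlotinib replicate 3. Their median, 0.04, was -0.07 without DMSO replicate 3, -0.01 without erlotinib replicate 1 and -0.04 without erlotinib replicate 2. The MYC antagonist genes MXI1 and MXD4 rose 1.85-fold and 1.58-fold, and the antiproliferative gene BTG1 rose from 9.76 ± 0.413 to 15.2 ± 1.35 TPM.

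In the list of ribosome biogenesis genes and MYC targets, 11 of 20 measured genes fell and 9 did not pass, 15 fell adjusted over the list alone, and 19 fell with the replicate block (median -0.33, camera adjusted p = 1.9e-06; adjusted p = 0.187 with an estimated correlation). The count was 5 without DMSO replicate 1, DMSO replicate 2 or erlotinib replicate 2, 7 without DMSO replicate 3 and 4 without erlotinib replicate 1. The nucleolar protein gene NOP56 fell from 219.6 ± 6.22 to 165.1 ± 9.51 TPM, NOP58 from 213.5 ± 11.4 to 170.8 ± 5.87 TPM and NOLC1 from 69.0 ± 5.36 to 54.2 ± 2.27 TPM. Among the 21 measured genes for cytosolic ribosomal proteins, 1 fell, none did adjusted over the list alone, and 5 fell with the replicate block (camera adjusted p = 0.275, and 0.0151 without DMSO replicate 2). That gene, RPS2, measured 3520 ± 67.0 and 3011 ± 44.9 TPM, and its call was lost without DMSO replicate 1, erlotinib replicate 1 or erlotinib replicate 2 (adjusted p 0.0762 to 0.124), while 2 genes of this list fell without erlotinib replicate 3. RPL3, RPL7A and RPSA were listed at 14 or fewer expected counts per library and were not tested.

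Genes controlled by ATF4, the transcription factor of the amino acid stress response, rose together. Of 19 measured, 17 rose, none fell and 2 did not pass, with 17 also adjusted over the list alone and 1 lower with the replicate block or without erlotinib replicate 3; the list median was 0.95 (camera adjusted p = 6.2e-14; adjusted p = 0.111 with an estimated correlation). PSAT1, a serine synthesis enzyme, rose from 141.7 ± 7.89 to 453.1 ± 19.0 TPM (log2 fold change 1.63 ± 0.07). SLC7A5, the large neutral amino acid transporter, rose from 262.0 ± 30.3 to 647 ± 37.5 TPM, and CHAC1 from 8.05 ± 1.17 to 42.0 ± 3.27 TPM. ATF4 itself, chosen after its values were seen, had a log2 fold change of 0.87 ± 0.09 (adjusted p = 0.000667). Members of the unfolded protein response list moved both ways: 2 of 15 rose and 4 fell, 5 and 7 adjusted over the list alone, and 5 and 8 with the replicate block (median -0.19, mean -0.03, camera adjusted p = 0.566). HERPUD1 and XBP1 rose, to 106.1 ± 5.75 and 144.3 ± 7.81 TPM from 47.4 ± 3.03 and 78.5 ± 5.51. The endoplasmic reticulum proteins PDIA4 and CALR fell, from 243.9 ± 4.31 to 187.2 ± 5.87 TPM and from 686.9 ± 20.01 to 536.9 ± 18.6 TPM. The number lower was 2 without DMSO replicate 1, erlotinib replicate 1 or erlotinib replicate 2, and 7 without erlotinib replicate 3. The sign of this list depends on the test, since camera placed it lower than other genes and fry placed it higher (fry adjusted p = 0.288).

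Antioxidant genes of the NRF2 list rose in 14 of 16 cases and fell in none, with the same 14 and 0 adjusted over the list alone and 1 lower with the replicate block (median 0.53, camera adjusted p = 1.99e-08; adjusted p = 0.147 with an estimated correlation). AKR1B10, an aldo-keto reductase, rose from 692.1 ± 49.7 to 1424 ± 112 TPM, and PGD, of the pentose phosphate pathway, from 230.4 ± 8.63 to 409.5 ± 21.5 TPM. AKR1C3 and AKR1C2 rose 2.59-fold and 2.12-fold, but these paralogs are similar in sequence and the split of reads among such genes is uncertain. Targets of the aryl hydrocarbon receptor rose in 5 of 7 cases and fell in none, with 5 adjusted over the list alone (median 1.06, camera adjusted p = 3.38e-05; adjusted p = 0.103 with an estimated correlation). CYP1B1 rose from 57.9 ± 5.57 to 123.9 ± 6.87 TPM and AHRR, the receptor's repressor, from 7.02 ± 0.812 to 9.98 ± 0.517 TPM. This list shares SLC7A5 with the ATF4 list and NQO1 with the NRF2 list. NQO1, chosen after its values were seen, measured 2927 ± 104 and 3386 ± 29.9 TPM (adjusted p = 0.142, and 0.0176 with the replicate block).

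Targets of FOXO factors, which are held inactive by AKT, rose in 11 of 19 cases and fell in none, with 11 adjusted over the list alone and 1 lower with the replicate block or without erlotinib replicate 3 (median 0.39, camera adjusted p = 0.000159; adjusted p = 0.117 with an estimated correlation). KLHL24 rose from 7.83 ± 1.00 to 20.5 ± 1.52 TPM, YPEL2 from 2.79 ± 0.422 to 7.84 ± 1.17 TPM, the repressor gene BCL6 from 48.7 ± 4.95 to 90.5 ± 4.62 TPM, and CCNG2, an atypical cyclin, from 10.1 ± 0.742 to 17.0 ± 0.745 TPM. In the BCL2 family, 5 of 14 genes rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.278). None of the family fell without DMSO replicate 1, erlotinib replicate 1 or erlotinib replicate 2, and 1 fell without DMSO replicate 2; the median, 0.06, was -0.01 without erlotinib replicate 3. Genes of the list that promote apoptosis and rose were BMF, from 19.6 ± 1.89 to 70.3 ± 7.71 TPM, BCL2L11 (BIM), from 20.75 ± 3.34 to 34.6 ± 2.91 TPM, PMAIP1 (NOXA), from 8.95 ± 0.40 to 16.8 ± 0.853 TPM, and HRK, from 4.38 ± 0.522 to 8.27 ± 0.331 TPM; the other proapoptotic genes of the list were not called higher, and 1 of them fell. The antiapoptotic genes BCL2 and BCL2L2, chosen after their values were seen, fell and rose, with log2 fold changes of -1.61 and 0.29. Among p53 targets, 5 of 16 rose and 3 fell, 6 and 4 adjusted over the list alone, and 5 fell with the replicate block. Without DMSO replicate 1 or erlotinib replicate 1 only 2 p53 targets rose, without DMSO replicate 2, DMSO replicate 3 or erlotinib replicate 2 only 3. The number of p53 targets lower was 1 without DMSO replicate 2, DMSO replicate 3, erlotinib replicate 1 or erlotinib replicate 2, and 5 without erlotinib replicate 3. TP53INP1 rose from 2.80 ± 0.233 to 9.52 ± 1.11 TPM and AEN fell from 32.7 ± 1.78 to 19.4 ± 1.54 TPM. For this list the median was -0.03 and the mean 0.01, and camera gave no call (adjusted p = 0.865); the median was 0.02 without DMSO replicate 3 and 0.04 without erlotinib replicate 2. Of 20 autophagy and lysosome genes, 5 rose, also adjusted over the list alone, and 8 rose and 2 fell with the replicate block (camera adjusted p = 0.0867, and 0.0307 without DMSO replicate 3). Without DMSO replicate 1 or 2 the number higher was 3, and without erlotinib replicate 3 the number lower was 1. SQSTM1, the autophagy receptor p62, rose from 390.8 ± 1.67 to 632 ± 8.40 TPM, and WIPI1 from 14.97 ± 1.33 to 25.2 ± 2.53 TPM.

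Metabolic lists moved in both directions within each list, and camera called none of them. Of 22 glycolysis and hypoxia genes, 4 rose and 5 fell, 4 and 8 adjusted over the list alone, and 5 and 8 with the replicate block (adjusted p = 0.379). Without DMSO replicate 1, 2 of these genes rose, and without erlotinib replicate 1, 3 fell. VEGFA rose from 27.4 ± 2.64 to 59.5 ± 0.286 TPM, PFKFB3 rose 1.41-fold, and PFKP, a phosphofructokinase, fell from 96.4 ± 5.23 to 64.6 ± 3.65 TPM. For cholesterol synthesis, 4 of 21 rose and 2 fell, 5 and 3 adjusted over the list alone, and 5 and 5 with the replicate block (adjusted p = 0.8). Without DMSO replicate 1 or erlotinib replicate 1, 2 cholesterol genes rose, and 1 fell without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2. INSIG1 and SC5D rose 1.45-fold and 1.28-fold, and ACAT2 fell from 186.3 ± 1.76 to 147.8 ± 9.40 TPM. For fatty acid synthesis, 2 of 12 rose and 3 fell, with the same counts adjusted over the list alone, and 4 rose with the replicate block. Without DMSO replicate 1, 1 fell. The elongase gene ELOVL6 fell from 13.4 ± 2.27 to 6.51 ± 1.27 TPM and the desaturase gene SCD rose from 72.7 ± 9.27 to 110.8 ± 10.7 TPM. The median of that list was 0.02 and its mean -0.05 (camera adjusted p = 0.910), and the median was -0.07 without DMSO replicate 3, -0.05 without erlotinib replicate 1 and -0.02 without erlotinib replicate 2.

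Of 16 interferon response genes, 4 rose and 3 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.423); MX1 rose from 5.19 ± 0.454 to 9.18 ± 0.413 TPM. Of the interferon genes, 2 rose without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2. None fell without DMSO replicate 2 or erlotinib replicate 1, and 1 fell without DMSO replicate 1, erlotinib replicate 2 or erlotinib replicate 3. Of 15 MHC class I presentation genes, 4 rose and none fell, with 4 adjusted over the list alone and 8 with the replicate block. None rose without DMSO replicate 1 or erlotinib replicate 1, and 1 rose without DMSO replicate 2 or erlotinib replicate 2. Camera did not call that list (adjusted p = 0.0867), but did with the replicate block (adjusted p = 0.0211) or without DMSO replicate 3 (adjusted p = 0.0134). Of 7 NF-kappa-B targets and cytokines measured, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.414), and BIRC3 rose from 5.86 ± 0.458 to 9.14 ± 0.760 TPM. With any one of the 6 libraries left out, none of these genes fell, and 1 rose without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2. In this group, 11 listed genes, CXCL1 and IL6 among them, were too low to test.

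Among signalling targets outside the ERK list, F3, the tissue factor gene of the YAP and TAZ list, fell from 84.6 ± 2.30 to 37.5 ± 1.27 TPM, while AJUBA rose 1.41-fold. In that list 1 of 12 rose and 3 fell, 2 and 3 adjusted over the list alone or with the replicate block (camera adjusted p = 0.350), and 1 fell without DMSO replicate 2 or erlotinib replicate 2, and 2 rose without erlotinib replicate 3. DKK1, a secreted WNT inhibitor, fell from 5.12 ± 1.09 to 1.95 ± 0.190 TPM; 1 of 7 WNT targets rose and 2 fell, 1 and 3 adjusted over the list alone (camera adjusted p = 0.481). None of the WNT targets rose without DMSO replicate 1, erlotinib replicate 1 or erlotinib replicate 2, and 1 fell without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 2 or erlotinib replicate 3. Their median, -0.27, was 0.04 without erlotinib replicate 3. Of 7 NOTCH targets, 1 rose and 1 fell, also adjusted over the list alone, and 3 fell with the replicate block or without erlotinib replicate 3 (camera adjusted p = 0.529); the receptor gene NOTCH3 fell 1.35-fold, a call lost in limma on TPM values (adjusted p 0.0683 to 0.105). None of the NOTCH targets rose without DMSO replicate 1, erlotinib replicate 1 or erlotinib replicate 2.

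Genes of the luminal list moved both ways. KRT18, a keratin of simple epithelia, fell from 4941 ± 233 to 2898 ± 124 TPM and KRT8 from 5566 ± 210 to 3869 ± 184 TPM, whereas the mucin gene MUC1 rose from 75.1 ± 4.58 to 137.8 ± 6.31 TPM. Of 10 luminal markers, 3 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.381). Of 12 basal markers, 2 rose and 2 fell, 2 and 3 adjusted over the list alone, and 5 fell with the replicate block (camera adjusted p = 0.362). The number of basal markers higher was 1 without DMSO replicate 1, DMSO replicate 2 or erlotinib replicate 2, and the number lower was 1 without DMSO replicate 2 or erlotinib replicate 1. KRT15 rose from 72.1 ± 1.39 to 132.1 ± 1.40 TPM and ITGB4, the integrin of hemidesmosomes, fell from 93.5 ± 9.68 to 57.7 ± 3.91 TPM. Of 10 squamous differentiation genes, 3 rose and 1 fell, 4 and 1 adjusted over the list alone, and 2 fell with the replicate block (camera adjusted p = 0.343); 1 rose without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2, and none fell without DMSO replicate 1, DMSO replicate 2 or erlotinib replicate 1. LCN2 rose from 489.8 ± 24.7 to 782.2 ± 65.8 TPM. Of 17 epithelial junction genes, 2 rose and 1 fell, also adjusted over the list alone, and 5 rose and 4 fell with the replicate block (camera adjusted p = 0.854). Of the junction genes, 1 rose without DMSO replicate 1, DMSO replicate 2, erlotinib replicate 1 or erlotinib replicate 2, and 2 fell without erlotinib replicate 3. ELF3 rose from 405.5 ± 8.38 to 650.4 ± 12.9 TPM and CLDN1 fell 1.46-fold. Of 10 mesenchymal genes, 3 fell and none rose, 3 and 1 adjusted over the list alone, and 3 and 2 with the replicate block (camera adjusted p = 0.197). The falling genes were of the extracellular matrix: TNC, from 21.6 ± 4.15 to 7.91 ± 0.966 TPM, THBS1, from 229.4 ± 46.2 to 135.2 ± 19.3 TPM, and TGFBI, from 21.8 ± 2.03 to 14.4 ± 1.34 TPM.

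Markers of other cell types were mostly too low to test. In the fibroblast list 2 of 10 genes were measured: COL1A1 at 4.55 ± 0.372 and 4.59 ± 0.676 TPM and COL5A1 at 77.6 ± 3.00 and 67.3 ± 12.2 TPM in DMSO and erlotinib (adjusted p = 0.232, 0.0182 with the replicate block and 0.0029 without erlotinib replicate 3). Of 14 blood and endothelial genes 4 were measured, and 1 of them, CDH5, fell from 102.7 ± 13.8 to 61.9 ± 4.66 TPM, also adjusted over the list alone; 2 fell without erlotinib replicate 3. None of the 13 mitochondrially encoded genes was measured.

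**Figure D2:**
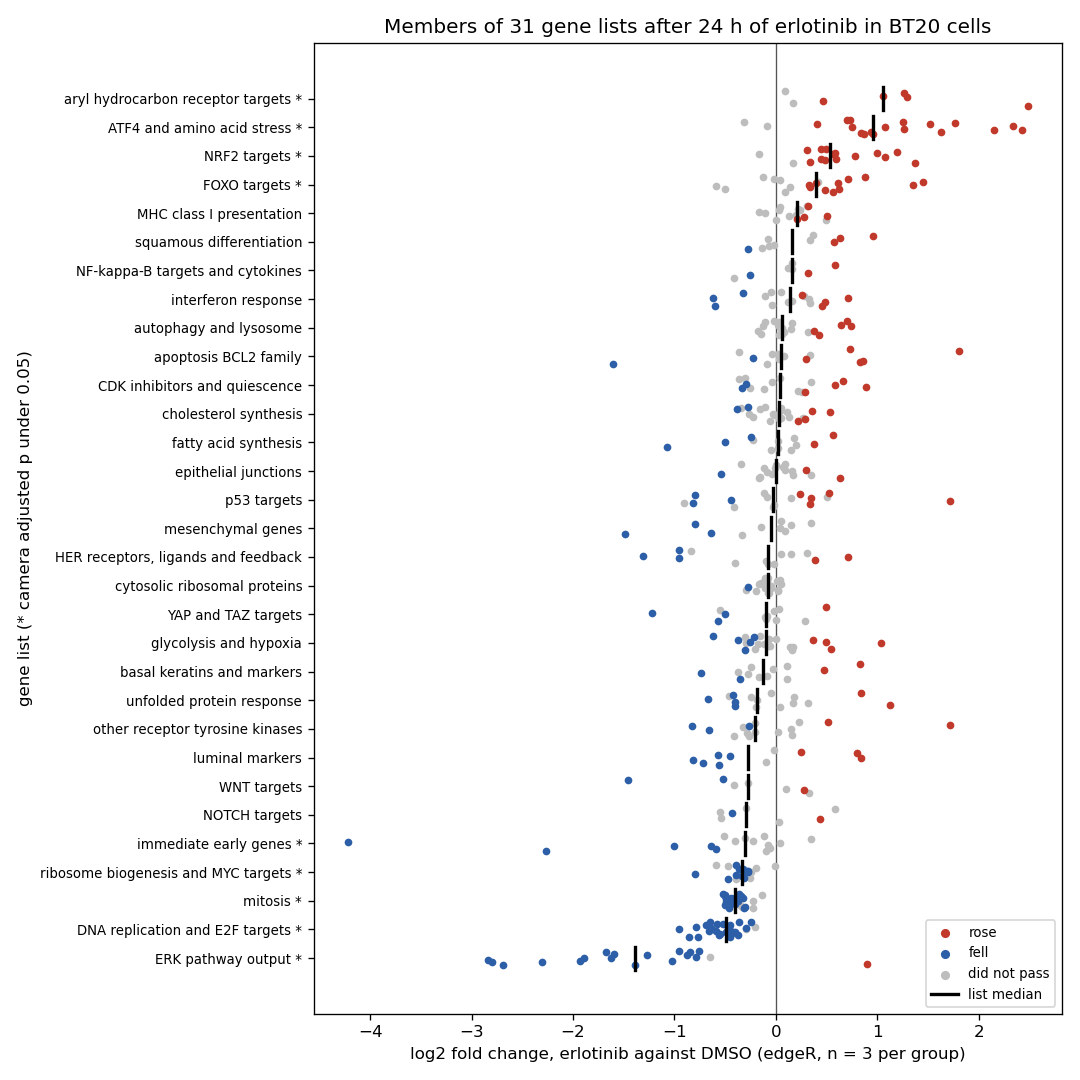
Log2 fold change (erlotinib against DMSO, edgeR, n = 3 libraries per group) of each measured member of 31 gene lists; a point is a gene, red rose, blue fell, grey did not pass, a black bar is the list median and an asterisk marks a camera adjusted p under 0.05. The ERK output list has the lowest median, -1.39, and the aryl hydrocarbon receptor list the highest, 1.06.

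Over the 31 lists with at least 5 measured members, camera with a preset correlation called 4 higher (ATF4, NRF2, aryl hydrocarbon receptor, FOXO) and 5 lower (ERK output, immediate early, DNA replication, mitosis, ribosome biogenesis and MYC targets). With the correlation estimated for each list none was called, and 8 of the lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes, called 12 lists higher and 5 lower. Camera also called up to 10 lists when the 6 libraries were split in ways that mix the treatments. Those splits divide the treatments unequally and keep part of their difference, so a list called there need not be a false call. All 9 lists called in the treatment split had a larger absolute median shift there than in any other, by 1.08 to 2.71 times. They were picked by their call in that split, so this is no independent test. The counts of individually tested members carry the description above.

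The authors' deposited table of their own DESeq2 comparison held 16198 genes and called 1236 higher and 1356 lower at an adjusted p under 0.05. Of the 13312 genes tested here, 98.2% had the same sign in the authors' deposited table. The calls overlapped in 2405 genes, all with the same sign; among the genes tested here, 179 were called in the authors' deposited table alone and 360 in the edgeR fit alone. Log2 fold changes in the authors' deposited table were smaller in size for many named genes, such as -3.38 for EGR1 and 2.28 for ASNS. Size of the change was not the only factor, as some genes with low or uneven counts differed more. The authors' values were 0.29 for RAB4B-EGLN2, -0.62 for DUSP6 and 0.76 for DDR2, against 3.93, -1.93 and 1.71 in the edgeR fit. DESeq2 as run here gave 4.11 for RAB4B-EGLN2. For CDC20 both were -0.50.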

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

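The alternatives that leave out both replicate 3 libraries or use length offsets, and all settings for gene families, were chosen after seeing the data. Of 131 called genes that the text names, with BCL2 and BCL2L2 left aside, 120 kept their call in every alternative and 0 changed direction. NR4A1 (adjusted p = 0.0669) and AHRR (0.0614) lost their calls in limma without a filter. Called lists kept their side of the threshold in every alternative except an estimated correlation, which called 0 lists higher and 0 lower; fry called 12 higher. Genes higher and lower numbered 2818 and 2844 with the replicate block, 2681 and 2849 with both replicate 3 libraries left out, and 2875 and 3073 with length offsets and replicate block. In limma, genes lower numbered 816 on log2(TPM + 1), 806 on log2(TPM + 0.1) and 706 without a filter; genes at least 2-fold higher numbered 109 and, without a filter, 107, and at least 2-fold lower 63 and 62, where the pseudocount shrinks folds of low genes. Leaving out 1 library gave 688 to 1627 genes higher, 637 to 1734 lower, 168 to 219 at least 2-fold higher, 105 to 196 at least 2-fold lower, 4 to 6 lists higher and 5 to 6 lower. The share of genes on the authors' side of zero, 98.2%, was 99.02% with DESeq2, 99.05% with its size factors, 98.8% without a filter, 90.94%, 90.86% and 92.01% in limma, 91.95% with both replicate 3 libraries left out, 96.55% and 96.71% with length offsets alone and with the block, and 89.1% to 94.74% without 1 library. Among the lists fixed in advance the replicate block changed only the call of MHC class I presentation, among the added families only that of complex I subunits, and of the named genes the calls of EPHA4, ERBB2, COL5A1 and NQO1. The cause of the changes was not tested.

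Reversed directions were found for results without a call. Log2 fold changes turned for EGFR (-0.297 to 0.102 without 1 library), EGF (-0.022 to 0.577), LRIG1 (-0.111 to 0.014; 0.017, 0.019 and 0.017 in limma), LRIG3 (-0.088 to 0.192) and COL1A1 (-0.184 to 0.049; 0.007 in limma). The direction of the list test, which need not be the sign of the median, turned for 5 lists, given here with medians of log2 CPM differences: fatty acid synthesis (0.012 with the replicate block, -0.069 to 0.058 without 1 library), p53 targets (-0.031 with the block, -0.047 to 0.041 without 1 library, -0.053 with both replicate 3 libraries left out), cholesterol synthesis (-0.034 with both left out), cytosolic ribosomal proteins (-0.153 to 0.014 without 1 library) and the unfolded protein response (-0.189, higher in fry). The median of edgeR's fold changes itself changed sign in at least 1 alternative for 11 of the 22 tested lists without a call and for 0 of the 9 with one. Its lowest and highest values were -0.17 and 0.01 for HER receptors and ligands, -0.07 and 0.12 for CDK inhibitors, -0.05 and 0.07 for cholesterol synthesis, -0.07 and 0.07 for fatty acid synthesis, -0.43 and 0.04 for WNT targets, -0.02 and 0.05 for epithelial junctions, -0.25 and 0.13 for mesenchymal genes, -0.13 and 0.23 for squamous differentiation, -0.06 and 0.04 for p53 targets, -0.01 and 0.19 for the BCL2 family, and -0.16 and 0.03 for cytosolic ribosomal proteins.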

Other observations

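The tests of read allocation, of the length trend of replicate 3 and of endoplasmic reticulum stress were chosen after the result was seen, as were the gene families and the genes named as their examples.

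Gene families beyond the fixed lists, 20 in all, were tested with camera, and most of those it called are described; the integrins share 2 members, the amino acid carriers 3, the proteasome subunits 3 and the serpins 1 with the fixed lists. Of 20 cytosolic tRNA synthetase genes, 12 rose and 2 fell (median log2 fold change 0.52): GARS rose from 119 ± 5.54 to 252 ± 11.3 TPM (SD, n = 3), CARS from 75.6 ± 5.02 to 187 ± 4.75, and MARS and WARS by 1.04 and 1.14 on the log2 scale. Their mitochondrial counterparts had 5 of 17 lower and none higher, such as AARS2 from 28.1 ± 1.63 to 21.7 ± 1.3 TPM. Among 26 amino acid carriers 11 rose and 2 fell; the glycine transporter SLC6A9 rose from 7.94 ± 0.472 to 40.4 ± 1.20 TPM and the glutamine transporter SLC1A5 from 215 ± 4.17 to 451 ± 14.8. A hypothesis written before its test, on a family chosen after the data were seen, was that the cytosolic synthetases move with the ATF4 list. Camera placed them higher than other genes (adjusted p = 0.00115 over 20 families, and 0.365 with an estimated correlation). The test compares them with other genes and does not ask whether they move with the ATF4 list. Camera also called amino acid carriers, histones and serpins higher, so the call is not particular to the synthetases.

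Tubulins fell in 9 of 18 cases and rose in none, among them TUBA1B from 2790 ± 78.3 to 1860 ± 139 TPM and TUBB6 by -0.97 on the log2 scale, and 8 of 9 chaperonin CCT subunits fell, with CCT4 at 448 ± 12.8 and 352 ± 12.4 TPM. Of 15 integrins, 6 fell and 1 rose; ITGA2 went from 19.9 ± 3.94 to 8.09 ± 1.08 TPM and ITGA6 from 50.7 ± 3.71 to 33.5 ± 1.61. Histone genes rose in 7 of 38 cases and fell in 1, HIST2H2BE from 27.8 ± 1.61 to 75.1 ± 3.73 TPM. Mitochondrial ribosomal protein genes had 7 of 77 lower, none higher and 70 not called. Camera adjusted p-values were 4.09e-05 for tubulins, 0.00392 for CCT subunits, 0.0122 for integrins, 0.00625 for histones, 3.78e-05 for mitochondrial ribosomal proteins, 0.00392 for mitochondrial synthetases and 0.000274 for carriers, and with an estimated correlation they were 0.250, 0.612, 0.365, 0.612, 0.620, 0.250 and 0.353. Of 5 metallothioneins 2 fell (camera adjusted p = 0.0216; adjusted p = 0.365 with an estimated correlation). The metallothionein call was lost without DMSO replicate 3 (adjusted p = 0.0663), erlotinib replicate 3 (0.0588) or both replicate 3 libraries (0.143), and with length offsets and replicate block (0.0852). The histone call was lost in fry (adjusted p = 0.0554) and without erlotinib replicate 3 (0.0649), that of mitochondrial ribosomal proteins in fry (0.171), and that of integrins without both replicate 3 libraries (0.0748). Medians moved over 1.5 times without 1 library: integrins to -0.14 without erlotinib replicate 3, histones to 0.23 without DMSO replicate 2, carriers to 0.28 and 0.27 without erlotinib replicate 1 and 2, and mitochondrial ribosomal proteins to -0.11 without DMSO replicate 3. Camera also called proteasome subunits lower, serpins higher and translation initiation factors lower (adjusted p = 0.00625, 0.00673 and 0.0312; adjusted p = 0.697, 0.350 and 0.612 with an estimated correlation). Complex I subunits were called lower with the replicate block (adjusted p = 0.0407, and 0.181 without it). Without the block none of the 37 members was called, and camera with an estimated correlation gave an adjusted p of 0.927. Many histone genes and tubulins are similar in sequence to others of their family, so the division of reads within these families is uncertain.

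Camera called the ATF4 list higher (adjusted p = 6.2e-14; adjusted p = 0.111 with an estimated correlation) and did not call the unfolded protein response list. A length trend between the treatments is argued against by 17 ATF4 members still called higher with length offsets and the replicate block, and the replicate 3 libraries by 17 called higher without them. General endoplasmic reticulum stress would raise both lists and stays open: the median of the unfolded protein response list was -0.191 against 0.95 for the ATF4 list, but it lay below 0.3, taken as a rise, by less than the SD over its members (0.494), and its members went both ways, 2 higher and 4 lower, or 5 and 8 with the replicate block. An effect of erlotinib, at the EGFR or elsewhere, also stays open, as 1 dose and 1 time point cannot divide them.

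Replicate 3 lay apart from replicates 1 and 2 in both treatments. Its deviation followed effective transcript length across genes (Spearman rho -0.562 in DMSO and -0.411 in erlotinib), with medians of 0.22 and 0.16 in the 2663 genes with the shortest transcripts and -0.20 and -0.14 in the 2663 with the longest. Thinning all libraries to the smallest total left the weaker rho at -0.41, which argues against the number of counts alone as the cause. Thinning keeps each gene's expected share of its library, so it cannot test other differences that go with depth. Length is not the whole of it, because the deviations of both replicate 3 libraries still correlated at 0.432 after the trend was removed, against 0.519 before. Library or RNA quality differences that follow length may contribute, no batch is named in the labels, and no biological explanation was tested.

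Some of the most extreme fold changes sit at overlapping genes. BLOC1S5 had 57.3, 78.0 and 56.1 expected counts in DMSO and 0 in every erlotinib library; PHOSPHO2-KLHL23 had 0 in every DMSO library and 41.0, 61.4 and 45.0 in erlotinib, while its partner KLHL23 had a log2 fold change of -1.30. Of 106 readthrough loci, 9 held a gene called at 2-fold or more, with BLOC1S5 in 2 of them; at 6 no called gene alone could move the counts summed over the locus by 1.5-fold, so a steady sum tells nothing there, those of BLOC1S5 included. At the other 3, the sum changed by under 1.5-fold in 1 (33.3%), that of KLHL23, where reassignment of reads between overlapping models may contribute and stays open. At STON1-GTF2A1L, FAM24B-CUZD1, RTEL1-TNFRSF6B and PALM2-AKAP2 the sums changed by 1.66, 0.85, -0.94 and -1.08 on the log2 scale, without overlap between the treatments. Reassignment among the summed genes alone would leave a sum unchanged, so it is argued against as the whole cause there. These are the called loci whose sums changed by 1.5-fold or more, so their choice fixed this outcome and it is no independent test. FAM24B-CUZD1 and PALM2-AKAP2 are among the 6 loci above, where only a changed sum is informative. No biological explanation was tested.

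The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. Every split but the real one puts both treatments in each group, so the treatment difference adds to the spread within groups. This lowers the gene calls in those splits, with or without the replicate block. They therefore do not show how many genes would be called without a treatment effect. The number with results as large as the treatment split, itself included, was 1 for genes changed in either direction (2765, highest other 0), 1 for genes changed at least 2-fold (321, highest other 0) and 4 for gene lists called by camera (9, highest other 10). In the other splits edgeR found between 50 and 1381 genes at an unadjusted p under 0.05, against 4630 in the real one, and DESeq2 called 0 to 33 genes against 2593. The 3 others that part every replicate pair gave 0 genes with the replicate block too, against 5662.

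Of 77 cytosolic ribosomal protein genes, RPL3, RPL7, RPL7A and RPSA were listed at 14 or fewer expected counts in every library, while the median over these genes was 7920.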
